A study of Caenorhabditis elegans with 54 samples.

How the data were processed

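The study measured polyadenylated RNA from whole worms of the laboratory strain N2 of Caenorhabditis elegans, exposed from the L4 larval stage at 20 °C, in 54 libraries: 3 foods, 3 Bt conditions and 2 times, with 3 libraries per group. Groups and replicate numbers were taken from the sample labels, and each column of the deposited table was matched to its sample through the sample's description, which left 0 columns unused. The deposited table holds raw read counts per gene under C. elegans sequence names, not divided by depth or gene length. Per the labels, the submitters aligned reads with STAR 2.5.3a. The counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Names of genes came from the Ensembl annotation of the reference assembly: of 46589 gene entries 46180 matched 1 gene, 3 matched several and 406 matched none, the last group holding 0.229% of all counts.

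Total counts per library ran from 18450550 to 38722292, with 3 libraries under 25000000. Replicates of a group correlated at 0.926 to 0.993 in log2 CPM and all differed by more than sampling noise, the lowest chi-square per degree of freedom being 10.2. The biological coefficient of variation was 36.7% in the fit, with 36 residual degrees of freedom.

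Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 18 groups, which left 17855, and libraries were scaled by TMM. One quasi-likelihood model with a mean per group was fitted to all 54 libraries. In it 23 comparisons were tested two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. They set BT247 against BT407 on each food, each Pseudomonas food against OP50 without Bt and under BT247, the BT247 responses of these foods against each other, MYb115 against MYb11, BT407 against no Bt on OP50, and 24 h against 12 h on OP50. Levels are CPM on the TMM-scaled library sizes, and log2 CPM used a prior count of 2.

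Gene lists covering immune effectors and pathogen responses, stress and detoxification, metabolism, reproduction and tissue markers were tested with camera (preset correlation 0.01, lists of at least 4 tested genes) and with camera under an estimated correlation, through limma 3.58.1. Members past the threshold were counted over all genes and adjusted over the list alone. The preset correlation gave 280 list calls and the estimated one 16, so the text gives the latter's adjusted p, and a list passes as a set only where it is under the threshold. Comparisons, lists, the rule for naming genes and the alternatives in the plan were fixed before the data were examined. That rule took, per comparison, genes past the threshold without overlap between the groups (in 10% of chance orderings 3 against 3 do not overlap) and with at least 1 CPM in the higher group: up to 8 per direction called at both times, 4 per direction at each time, and the 4 members of each list with the smallest adjusted p. The differences between responses carried no such overlap condition. The text names a part of these genes, preferring those whose calls held when single libraries were left out. That preference was made after the values were seen.

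The pipeline was tested on simulated data in which 100 genes were changed 2-fold and another 100 were changed 4-fold. Of the 2-fold genes 45% were recovered in the comparison on OP50 at 12 h and 35% in that of MYb11 with OP50 at 24 h, and of the 4-fold genes 69% and 75%. False calls made up 8.8% and 4.3% of all calls in these comparisons, so the first lay above the nominal level. A count of 0 in a group was set against a floor of 3 counts over that group, which covers counting error only.

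Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, a fit of the compared groups only, a replicate block, and each library left out in turn. After the data had been seen, 2 surrogate variables from sva 3.50.0, the removal of the 3 libraries under 25000000 counts and the removal of the 4 libraries above 60 on the second principal component at 12 h were added. Other divisions of the same libraries were fitted for every comparison, all 10 for 3 against 3 and 40 for each difference between responses. Python 3.11.15 mapped the columns and drew the plots.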

Results

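To follow how the bacterial food of Caenorhabditis elegans bears on its transcriptional response to a pathogen, transcript counts were compared between worms kept on Escherichia coli OP50, on Pseudomonas lurida MYb11 or on Pseudomonas fluorescens MYb115. On each food the worms met the pathogenic Bacillus thuringiensis strain BT247, the comparator strain BT407 or no B. thuringiensis (Bt), for 12 h or 24 h. Each of the 18 groups held 3 libraries. Log2 fold changes are given with a standard error worked back from the edgeR quasi-likelihood test, and levels as mean counts scaled to library size (CPM). That error is the size of the log2 fold change divided by the square root of its F statistic. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples. Because the handling of strands and of reads matching several genes is not given in the sources used here, antisense reads or reads from near-identical copies (such as the vitellogenins) may contribute to a gene's count.

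On OP50, genes changed in both directions under BT247. The CUB-domain gene C17H12.8 rose from 28.6 to 818 CPM at 12 h (log2 fold change 4.84 ± 0.61) and from 9.3 to 1630 CPM at 24 h (7.46 ± 0.69). The C-type lectin gene clec-67 rose by 5.10 ± 0.58 and 6.25 ± 0.61 on the log2 scale at 12 h and 24 h. Among lysozyme genes, lys-1 (3.22 ± 0.53 and 4.66 ± 0.57), lys-2 (3.84 ± 0.72 and 6.29 ± 0.81) and lys-3 (7.80 ± 0.91 and 5.43 ± 0.81) went up. In contrast, lys-4 (-4.32 ± 0.75 and -4.30 ± 0.74) and lys-5 (-3.54 ± 0.88 and -3.97 ± 0.84) went down. The protease gene cpr-3 (5.41 ± 0.54 and 5.66 ± 0.55), the glutathione S-transferase gene gst-22 (3.62 ± 0.39 and 3.74 ± 0.39) and the glucuronosyltransferase gene ugt-44 (3.88 ± 0.39 and 3.13 ± 0.38) were higher at both times. The claudin-like gene clc-13 had no count in the BT407 libraries at 12 h and 22.9 CPM under BT247, at least 700-fold above a floor of 3 counts over the group. Genes that fell at both times included cyp-25A1, a cytochrome P450 gene (-5.09 ± 0.87 and -3.63 ± 0.75), the metallothionein gene mtl-2 (-3.54 ± 0.77 and -4.63 ± 0.81) and the saposin-like gene spp-1 (-2.15 ± 0.46 and -3.34 ± 0.49).

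At an adjusted p of 0.05, 1653 genes were higher and 795 lower under BT247 on OP50 at 12 h, and 717 were higher and 168 lower at 24 h. Both times shared 510 higher genes against 66.4 under independence and 52 lower genes against 7.5. Another 4 genes went from up to down and 7 the other way. Single libraries set the size of the 12 h count of 2448: it was 1344 without OP50 BT247 replicate 1, 3960 without replicate 2 of that group, and 1551, 1514 and 1490 without OP50 BT407 replicates 1, 2 and 3. With 2 surrogate variables the 12 h split turned to 1212 higher and 1290 lower genes. Without the 4 libraries that stood apart the count was 1479.

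**Figure D1:**
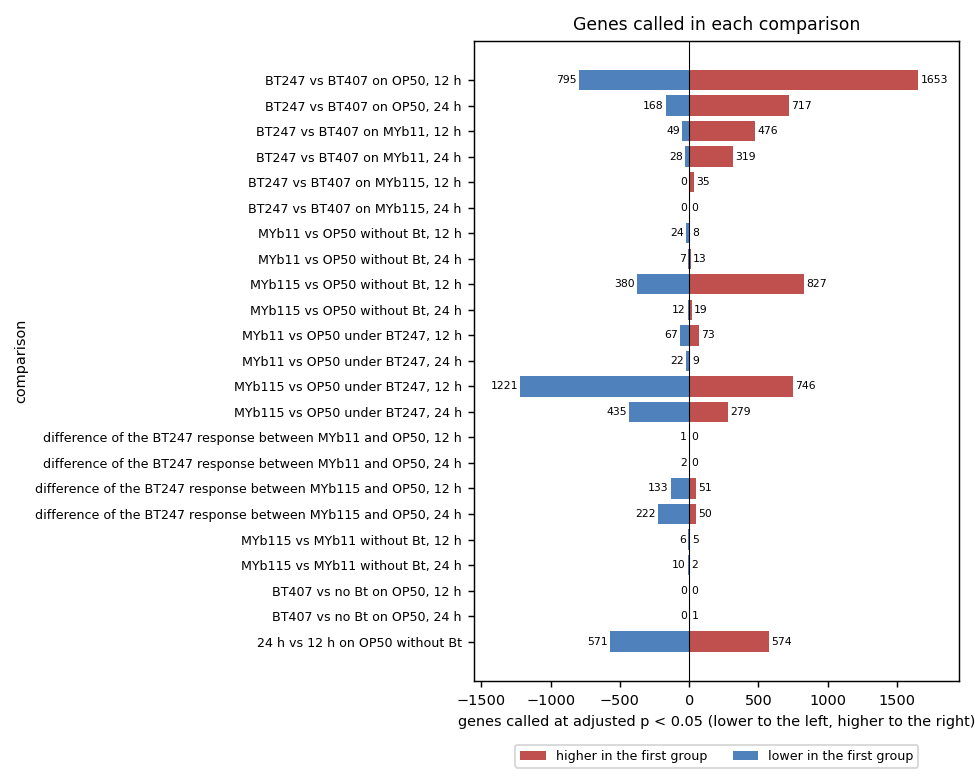
Number of genes called at an adjusted p of 0.05 in each of the 23 comparisons, higher genes to the right and lower genes to the left. BT247 on OP50 at 12 h gave 1653 higher genes and BT247 on MYb115 at 24 h gave 0.

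By gene list, targets of the p38 kinase PMK-1 were among the clearest movers on OP50. At 24 h 11 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median log2 fold change of 4.465. The set test held with an estimated correlation (adjusted p = 0.000107). They included irg-4 (6.30 ± 0.79) beside C17H12.8, clec-67 and lys-2. At 12 h 9 of the 13 were higher (9 up and 1 down adjusted over the list alone; adjusted p = 0.0987 with an estimated correlation). The ZIP-2 and translation-inhibition list had 4 of 9 genes higher at 24 h (6 adjusted over the list alone; adjusted p = 0.00616 with an estimated correlation), among them irg-7 (2.16 ± 0.37) and irg-8 (6.76 ± 1.24). Lysozymes split, with 4 of 13 up and 5 down at 12 h and 4 up and 7 down at 24 h (5 and 5, then 4 and 8, adjusted over the list alone; adjusted p = 0.858 and 0.974 with an estimated correlation). Among them lys-8 rose from 118 to 254 CPM at 12 h and from 105 to 450 CPM at 24 h. The intracellular pathogen response list, whose members include ubiquitin ligase parts, had 36 of 45 genes higher at 12 h (39 adjusted over the list alone) and 17 at 24 h (28), with none lower. Its ligase genes skr-3 (1.88 ± 0.28 and 1.99 ± 0.28) and skr-4 (1.63 ± 0.23 and 1.03 ± 0.23) rose at both times. The set test ended with an estimated correlation (adjusted p = 0.0888 and 0.284). In the pore-forming toxin defence list 7 of 21 genes were higher at 12 h and 3 at 24 h, the same numbers adjusted over the list alone (adjusted p = 0.274 and 0.33 with an estimated correlation). Of its members ttm-1 rose by 1.23 ± 0.14 and 1.05 ± 0.14, and the kinase gene sek-1 was called at 12 h only (0.66 ± 0.16).

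Some metabolic and yolk genes were called lower under BT247 on OP50 at 12 h, though as sets none of the lists passed with an estimated correlation. Libraries differed along the same genes. The high end of the second principal component, which holds vit-3, vit-4 and fat-7, is where OP50 BT407 replicate 2 lay (82), while OP50 BT247 replicates 1 and 3 lay at -74.7 and -64.3. The 12 h calls of vit-2 (-2.32), vit-6 and acdh-2 (-4.67) ended in a fit of the compared groups only. At 24 h the median log2 fold change was -0.13 for the propionate shunt list and -1.30 for vitellogenins, with 0 genes of either called (0 and 2 lower adjusted over the list alone). In the propionate shunt list 5 of 9 genes were lower at 12 h (7 adjusted over the list alone; adjusted p = 0.0987 with an estimated correlation), among them acdh-2 (-4.66 ± 1.10), pmp-5 (-4.16 ± 0.80), ech-6 (-1.70 ± 0.26) and hach-1 (-1.54 ± 0.26). In the methionine and S-adenosylmethionine cycle list 12 of 19 were lower (13 adjusted over the list alone; adjusted p = 0.0834 with an estimated correlation). The desaturase gene fat-7 (-6.14 ± 1.07) and the elongase genes elo-2 (-2.20 ± 0.38) and elo-5 (-2.38 ± 0.41) fell. So did 4 of 6 vitellogenin genes (6 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation), including vit-6 from 20900 to 4360 CPM (-2.26 ± 0.54) and vit-2 (-2.28 ± 0.53). Of 14 body wall muscle markers 7 were lower (11 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), such as the troponin gene unc-27 (-0.89 ± 0.22). Of 71 cytochrome P450 genes 21 were up and 5 down at 12 h, and 4 up and 17 down at 24 h (26 and 7, then 6 and 22, adjusted over the list alone; adjusted p = 0.507 and 0.284 with an estimated correlation). Their mean log2 CPM at 12 h and 24 h was 1.67 and 1.62 under BT247, 1.08 and 2.25 under BT407 and 1.55 and 2.27 without Bt, so the comparator moved between the times more than the BT247 worms did.

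**Figure D2:**
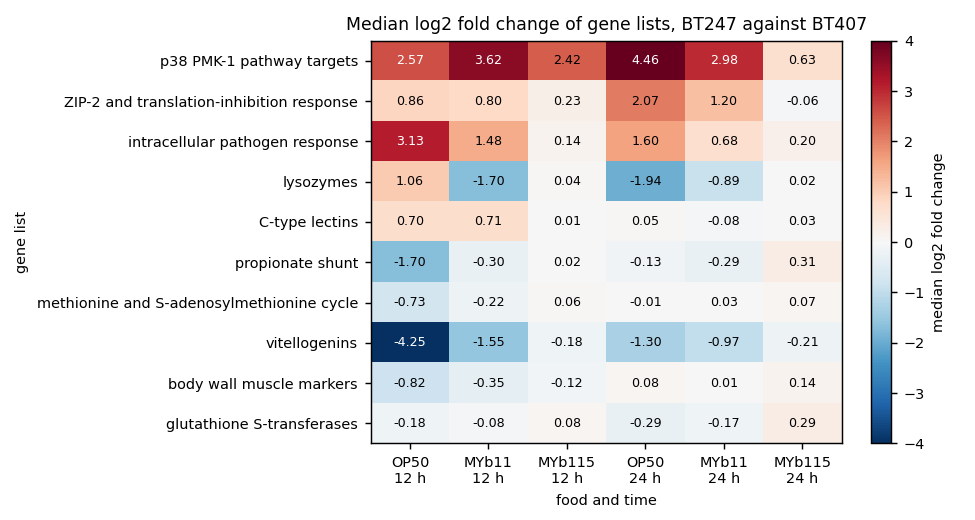
Median log2 fold change of BT247 against BT407 for 10 gene lists (vertical axis) on each food at 12 h and 24 h (horizontal axis), as colour and number. The PMK-1 target list stands at 4.465 on OP50 at 24 h.

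On MYb11 C17H12.8 rose by 4.27 ± 0.60 at 12 h and 5.21 ± 0.62 at 24 h on the log2 scale, clec-67 by 3.62 ± 0.54 and 4.11 ± 0.55, and sysm-1 by 6.87 ± 1.04 and 7.24 ± 1.04. Likewise irg-4 rose by 3.93 ± 0.70 and 4.94 ± 0.74 and cpr-3 by 4.47 ± 0.52 and 4.76 ± 0.53. The lysozyme genes lys-1 (2.79 ± 0.52 and 3.36 ± 0.54), lys-2 (3.94 ± 0.72 and 3.78 ± 0.72) and lys-3 (6.12 ± 0.84 and 5.54 ± 0.81) followed. The gene ttm-1 rose by 1.07 ± 0.14 and 0.85 ± 0.14. The esterase gene cest-1.2 (-1.95 ± 0.39 and -1.92 ± 0.39) and the dehydrogenase gene dhs-2 (-1.57 ± 0.31 and -1.59 ± 0.30) fell. PMK-1 targets counted 8 of 13 up at each time (10 and 11 adjusted over the list alone), and their set test held with an estimated correlation (adjusted p = 0.018 at 12 h and 0.000106 at 24 h). The ZIP-2 and translation-inhibition list had 3 of 9 genes up at 12 h (4 adjusted over the list alone) and 1 at 24 h (4), with an estimated-correlation adjusted p of 0.135 and then 0.00575. Intracellular pathogen response genes were up in 12 of 45 cases at 12 h (19 adjusted over the list alone), such as the cullin gene cul-6 (1.83 ± 0.31), and in 4 at 24 h (9). That list's adjusted p with an estimated correlation was 0.386 and 0.414. Calls that ended in a fit of the compared groups only were those of irg-4 (3.90) and cul-6 (1.80) at 12 h, of lys-1, lys-3 and cest-1.2 at 24 h, and of ttm-1 and dhs-2 at both times.

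In all, 476 genes were higher and 49 lower under BT247 on MYb11 at 12 h, and 319 were higher and 28 lower at 24 h. Of the higher genes, 445 were also higher on OP50 at 12 h (44.1 under independence). At 24 h 310 of the 319 were. The totals of 525 and 347 dropped to 260 without MYb11 BT247 replicate 1 at 12 h and to 188 without MYb11 BT247 replicate 1 at 24 h. These libraries held the fewest counts of the 54. The 24 h library also had the lowest mitochondrial share (0.19%) and the fewest genes with a count (19000) of all. A fit of the compared groups only called 168 higher and 14 lower genes at 12 h and 71 at 24 h.

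On MYb115 the response to BT247 was small and was called at 12 h. C17H12.8 rose from 19.1 to 254 CPM (3.73 ± 0.58) and clec-67 from 5.55 to 60.5 CPM (3.44 ± 0.54), and both calls held whichever library was left out. Both ended in a fit of the compared groups only (3.71 and 3.42), where the 12 h count was 0. PMK-1 targets were the leading list, with 5 of 13 up at 12 h (9 adjusted over the list alone; adjusted p = 7.07e-06 with an estimated correlation). This test sets a list against the other genes, so its p does not compare response size between foods. Under BT247 at 12 h the mean log2 CPM of the list was 3.80 on MYb115 (SD 0.92) and 5.35 on MYb11 (SD 0.28). At 24 h 0 of the 13 were called (1 up adjusted over the list alone; adjusted p = 0.402 with an estimated correlation), and C17H12.8 changed by 2.54 ± 0.56 without a call. At 12 h 35 genes were higher and 0 lower, 34 of them also higher on OP50 (3.2 under independence). DESeq2 called 63, a fit with 2 surrogate variables 80, and the fit without the libraries that stood apart 3. The count became 60, 17 and 3 without MYb115 BT247 replicates 1, 2 and 3, and 5, 3 and 11 without MYb115 BT407 replicates 1, 2 and 3. At 24 h edgeR called 0 genes, with 165 at an unadjusted p under 0.05 and a smallest adjusted p of 0.424. DESeq2 called 2, and 1 gene was called without MYb115 BT247 replicate 2.

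To compare response size with genes chosen on other libraries, the 717 genes higher on OP50 at 24 h were read at 12 h. Their mean log2 CPM was higher under BT247 than under BT407 by 2.06 ± 0.11 (standard error, n = 3 per group) on OP50, 1.70 ± 0.23 on MYb11 and 0.60 ± 0.12 on MYb115. On MYb115 86.8% of these genes still moved in the same direction. The 1653 genes higher at 12 h, read at 24 h, gave 1.06 ± 0.17, 0.80 ± 0.36 and 0.24 ± 0.39 on the same foods. The OP50 and MYb115 responses thus differed by 1.46 ± 0.16 at 12 h, and at 24 h by 0.82 ± 0.42, which is under 2 standard errors. At 24 h the mean of the 1653 genes on MYb115 was 2.37 without Bt, above BT247 (2.1) and BT407 (1.86). On MYb11 it was 2.04 without Bt, between BT247 (2.37) and BT407 (1.58). On OP50 it was 1.78 without Bt, 2.87 under BT247 and 1.81 under BT407. BT407 was tested against no Bt on OP50 only. Both sets were chosen for rising on OP50, which favours OP50. With genes chosen on MYb11 instead, the 319 higher at 24 h and read at 12 h gave 2.99 ± 0.09 on OP50, 2.58 ± 0.30 on MYb11 and 1.02 ± 0.25 on MYb115. The 476 higher on MYb11 at 12 h and read at 24 h gave 2.63 ± 0.10, 2.04 ± 0.37 and 0.40 ± 0.34. Even the 35 genes higher on MYb115 at 12 h gave 5.54 ± 0.13 on OP50 at 24 h and 1.07 ± 0.47 on MYb115. In the sets of higher genes chosen on OP50, all 3 MYb115 libraries under BT247 lay below all 3 OP50 libraries at each time. This gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.2 over 8 such exact tests. Lower genes were read in the same way. At 12 h the 168 from 24 h gave -0.65 ± 0.09 on OP50, -0.82 ± 0.22 on MYb11 and -0.02 ± 0.24 on MYb115. At 24 h the 795 from 12 h gave -0.12 ± 0.11, -0.23 ± 0.18 and 0.07 ± 0.17. By the means alone, the order of OP50, MYb11 and MYb115 by response size was thus seen for higher genes only. Its step from OP50 to MYb11 was not established. Over higher genes chosen on OP50, the BT247 libraries of these foods gave a two-sided exact permutation p of 0.3 at 12 h and 0.2 at 24 h. Over the 1653 genes at 24 h, MYb11 and MYb115 (0.80 ± 0.36 and 0.24 ± 0.39) were not clearly separated either. Across all genes tested, which are not independent replicates, the slope of the MYb11 response on the OP50 response was 0.55 at 12 h and 0.57 at 24 h (jackknife standard errors 0.237 and 0.30). That of MYb115 was 0.145 and 0.033 (0.094 and 0.096).

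**Figure D3:**
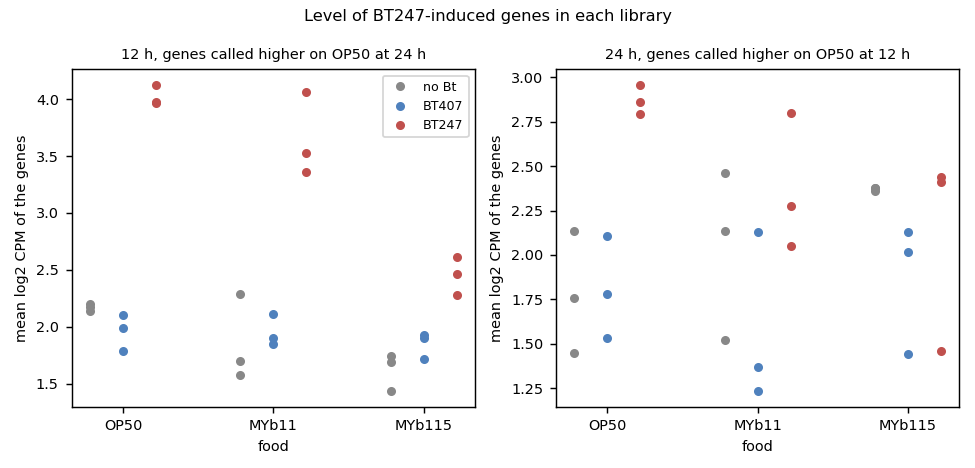
Mean log2 CPM per library (points) by food and Bt condition, at 12 h over the 717 genes higher on OP50 at 24 h and at 24 h over the 1653 genes higher on OP50 at 12 h. At 12 h the MYb115 BT247 libraries lie between 2.28 and 2.62, below the lowest OP50 BT247 library at 3.97.

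Tests of the difference between responses showed where MYb115 departed from OP50. At 24 h the BT247 response of clec-67 was smaller on MYb115 than on OP50 by a log2 difference of -5.68 ± 0.74, that of C17H12.8 by -4.91 ± 0.78 and that of lys-2 by -5.90 ± 0.98. The response was also smaller for cpr-3 by -4.56 ± 0.68, for ZK896.5 by -5.20 ± 0.66 and for skr-3 by -1.71 ± 0.39. Among PMK-1 targets 8 of 13 had a smaller response (11 adjusted over the list alone; adjusted p = 0.000133 with an estimated correlation), and among ZIP-2 and translation-inhibition genes 3 of 9 (5 adjusted over the list alone; adjusted p = 0.00118 with an estimated correlation). The acyl-CoA dehydrogenase gene acds-10 went the other way (1.38 ± 0.22). At 12 h 0 of 13 PMK-1 targets and 0 of 9 ZIP-2 and translation-inhibition genes were called, the same adjusted over the list alone (adjusted p = 0.879 and 0.926 with an estimated correlation). At that time 11 of 45 intracellular pathogen response genes responded less (32 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation). In turn 2 of 19 methionine cycle genes fell less on MYb115 (13 adjusted over the list alone; adjusted p = 0.0362 with an estimated correlation). The mean log2 CPM of this list was 7.06 under BT407 and 6.11 under BT247 on OP50, against 6.31 and 6.30 on MYb115, so it was already lower on MYb115 under BT407. F14F9.3 (-4.84 ± 0.72 at 12 h and -3.25 ± 0.69 at 24 h) and the carboxypeptidase gene pcp-1 (1.57 ± 0.27 at 12 h) kept their calls whichever library was left out. Fitting the compared groups only ended the 24 h calls of lys-2 (-5.88) and F14F9.3 (-3.24). ZK896.5 was also called at 12 h (-2.96 ± 0.63), a call that ended without MYb115 BT247 replicate 1 (-2.58). The call of ech-6 (1.68 ± 0.36 at 12 h) ended without OP50 BT407 replicate 1 (1.43), and that of elo-2 (2.37 ± 0.52) ended without OP50 BT247 replicate 1 (2.18) and without MYb115 BT247 replicate 1 (2.12).

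The MYb115 response differed from the OP50 response in 51 genes upward and 133 downward at 12 h, and in 50 and 222 at 24 h. With 2 surrogate variables the 12 h split turned to 225 upward and 136 downward. DESeq2 gave 136 and 271, a fit of the compared groups only 338 and 564, no filter 40 and 73, and the fit without the libraries that stood apart 43 and 78. At 24 h surrogate variables gave 511 in total. The 12 h total of 184 became 65, 107, 94, 116 and 85 without MYb115 BT247 replicates 1 and 2 and MYb115 BT407 replicates 1, 2 and 3, and 73, 113 and 86 without OP50 BT247 replicates 1 and 3 and OP50 BT407 replicate 3.

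For MYb11 against OP50 the responses differed in few genes, with F10D2.8 (-4.13 ± 0.62) and F48E3.2 (-3.16 ± 0.58) called at 24 h and the F-box gene fbxa-143 (-2.22 ± 0.39) at 12 h. DESeq2 called 6 genes at 12 h and 14 at 24 h, and surrogate variables 2 and 18. As sets, propionate shunt genes and methionine cycle genes fell less on MYb11 at 12 h (adjusted p = 0.0392 and 0.0141 with an estimated correlation), with 3 of 9 and 6 of 19 up adjusted over the list alone and 0 over all genes. Here too the foods differed more under BT407 than under BT247. The mean log2 CPM of the propionate shunt was 7.24 on OP50 and 4.93 on MYb11 under BT407, and 5.06 and 4.34 under BT247; that of the methionine cycle was 7.06 and 6.40, then 6.11 and 6.26. PMK-1 targets responded less at 24 h (adjusted p = 0.0463 with an estimated correlation), with 4 of 13 down adjusted over the list alone. This test does not tell a lower level under BT247 from a higher level under BT407. F10D2.8 kept its call whichever library was left out. With the compared groups only in the fit, the calls of all 3 genes ended (-4.12, -3.13 and -2.19). The fbxa-143 call ended without MYb11 BT407 replicates 1 (-2.29) and 3 (-2.05), MYb11 BT247 replicates 2 (-1.96) and 3 (-2.17), OP50 BT407 replicate 3 (-2.20) and OP50 BT247 replicates 1 (-2.21), 2 (-2.18) and 3 (-2.28). The F48E3.2 call ended without MYb11 BT247 replicates 1 (-3.14), 2 (-3.27) and 3 (-2.95), MYb11 BT407 replicate 1 (-2.67), OP50 BT247 replicates 1 (-3.12) and 3 (-3.10) and OP50 BT407 replicates 1 and 3 (-3.02 each).

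Without Bt, a group of genes was lower on both Pseudomonas foods than on OP50. The arginine kinase gene argk-1 stood at 325 CPM on OP50 at 12 h, and changed by -7.69 ± 0.90 on MYb11 and -10.16 ± 1.03 on MYb115, and at 24 h by -6.93 ± 0.91 and -6.26 ± 0.87. The cystathionine gamma-lyase gene cth-1 changed by -4.05 ± 0.32 and -4.46 ± 0.33 at 12 h and by -2.73 ± 0.31 and -2.27 ± 0.30 at 24 h. The C-type lectin gene clec-258 stood at 20.6 CPM on OP50 at 12 h, 0.0875 CPM on MYb11 and 0.0194 CPM on MYb115. On MYb115 the ABC transporter gene pmp-5 (-4.39 ± 0.82), the nuclear receptor gene nhr-114 (-2.67 ± 0.41) and the S-adenosylmethionine synthetase gene sams-1 (-2.70 ± 0.46) were lower at 12 h. On MYb11, str-7 (-4.19 ± 0.48 and -3.22 ± 0.47) and F22B8.4 (-6.13 ± 0.58 and -3.40 ± 0.51) were lower at 12 h and 24 h, and mtl-2 (-4.46 ± 0.81) at 24 h. On the same food nspg-7.2 (6.21 ± 0.71 and 6.74 ± 0.73) and the CUB-domain gene dod-24 (3.19 ± 0.43 and 3.42 ± 0.43) were higher at 12 h and 24 h.

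As lists at 12 h, the propionate shunt had 2 of 9 genes lower on MYb11 (6 adjusted over the list alone; adjusted p = 0.037 with an estimated correlation) and 3 on MYb115 (4 adjusted over the list alone; adjusted p = 0.609 with an estimated correlation). The methionine cycle list had 2 of 19 lower on MYb11 (9 down and 1 up adjusted over the list alone; adjusted p = 0.037 with an estimated correlation), and 6 lower and 1 higher on MYb115 (8 and 1 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). Fatty acid synthesis had 6 of 22 lower on MYb115 (9 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), and glutathione S-transferases 5 of 47 higher (5 adjusted over the list alone; adjusted p = 0.87 with an estimated correlation). In a fit of the compared groups only, the 12 h calls of argk-1, cth-1, clec-258, str-7 and nspg-7.2 on MYb11 and of pmp-5, nhr-114 and sams-1 on MYb115 ended. So did the 24 h calls of str-7, F22B8.4, dod-24 and mtl-2 on MYb11. Genes lower on both foods numbered 22 at 12 h against 0.51 under independence, and 7 at 24 h, and genes higher on both numbered 2 and 0. In 20 simulations of unchanged groups sharing the OP50 libraries no gene was shared. These fits used the 3 compared groups alone without a low-count filter, and genes were drawn independently. In fits of the compared groups only the real 12 h data gave 2 calls on MYb11 and 17 on MYb115. The simulations therefore do not show that the overlap exceeds noise in the shared OP50 libraries. The covariance of the fold changes was 0.422 against a simulated mean of 0.162 at 12 h and 0.292 against 0.147 at 24 h. No spread of the simulated values was kept.

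On MYb11 8 genes were higher and 24 lower than on OP50 at 12 h, and 13 and 7 at 24 h. On MYb115 827 were higher and 380 lower at 12 h, and 19 and 12 at 24 h. These counts depend on the method and on single libraries. On MYb115 at 24 h 4216 genes had an unadjusted p under 0.05. There DESeq2 called 537 higher and 135 lower, a filter of at least 1 CPM in 3 libraries gave 53 and 349, no filter 7 and 6, and a fit of the compared groups only 1 and 3. With 2 surrogate variables that split was 15 and 17. On MYb115 at 12 h DESeq2 called 1154 higher and 726 lower, the 1 CPM filter 281 and 402, no filter 177 and 188, and a fit of the compared groups only 3 and 14. Leaving out the 4 libraries that stood apart gave 432 and 94. On MYb11 DESeq2 called 65 genes at 12 h and 38 at 24 h, a fit of the compared groups only 2 and 3, and surrogate variables 65 at 12 h. For MYb11 at 12 h the count was 21, 16 and 789 without MYb11 replicates 1, 2 and 3 and 19 without OP50 replicate 3. At 24 h it was 95 and 11 without MYb11 replicates 1 and 2 and 13 without OP50 replicate 2. For MYb115 at 12 h it was 41 and 638 without MYb115 replicates 1 and 3 and 435, 160 and 605 without OP50 replicates 1, 2 and 3. At 24 h it was 13, 14 and 12 without MYb115 replicates 1, 2 and 3 and 13 and 6 without OP50 replicates 2 and 3.

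**Figure D4:**
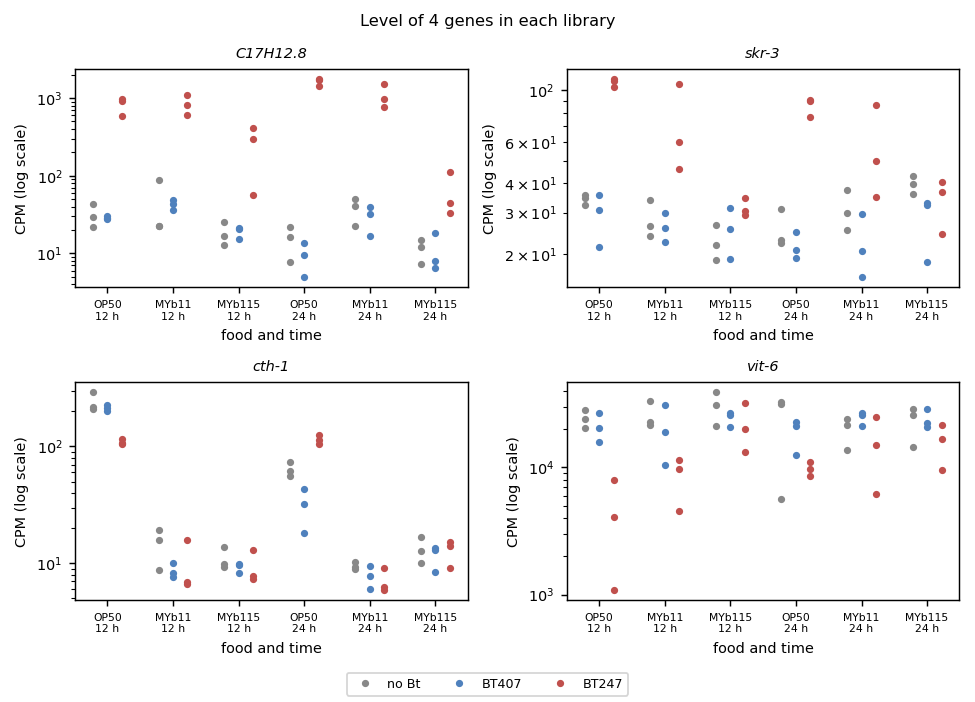
CPM per library (points, log axis) of C17H12.8, skr-3, cth-1 and vit-6 by food and time, coloured by Bt condition. Without Bt at 12 h, cth-1 averaged 241 CPM on OP50, 14.6 on MYb11 and 10.9 on MYb115.

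Between the Pseudomonas foods without Bt, F55G11.4 (-4.18 ± 0.62 at 12 h and -5.19 ± 0.66 at 24 h) and dod-24 (-3.44 ± 0.43 and -3.99 ± 0.44) were lower on MYb115 than on MYb11. At 24 h nspg-7.2 was lower (-4.14 ± 0.63), and at 12 h the peroxisomal thiolase gene daf-22 was higher (1.71 ± 0.25). Of the 11 hypoxia and hydrogen sulphide or cyanide response genes, 7 were higher on MYb115 at 24 h adjusted over the list alone and 0 over all genes (adjusted p = 0.0325 with an estimated correlation). The 12 h calls of F55G11.4 (-4.20), dod-24 (-3.47) and daf-22 (1.66) ended in a fit of the compared groups only. In total 5 genes were higher and 6 lower at 12 h, and 2 and 10 at 24 h. At 12 h DESeq2 gave 40 and 21, 2 surrogate variables 15 and 9, and the fit without the libraries that stood apart 23 and 3. At 24 h DESeq2 gave 8 and 16. A fit of the compared groups only called 0 at 12 h and 3 at 24 h. The 12 h count was 3, 73 and 26 without MYb115 replicates 1, 2 and 3 and 7 without MYb11 replicate 2, and the 24 h count was 4 without MYb115 replicate 2 or 3 and 7 without MYb11 replicate 2.

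Worms on MYb115 and on OP50 were also compared under BT247. At 24 h C17H12.8 stood at 63.3 against 1630 CPM (-4.69 ± 0.61), irg-4 differed by -5.28 ± 0.75, irg-7 by -2.02 ± 0.36, irg-8 by -5.18 ± 1.15, lys-1 by -3.98 ± 0.55, lys-2 by -5.04 ± 0.76 and clec-67 by -4.78 ± 0.57. The level of lys-8 was 105 against 450 CPM. The genes cpr-3 (-3.31 ± 0.49 and -4.97 ± 0.53), gst-22 (-2.02 ± 0.36 and -2.86 ± 0.37), skr-3 (-1.78 ± 0.28 and -1.34 ± 0.27), cul-6 (-1.94 ± 0.31 and -1.41 ± 0.30), clec-58 (-5.97 ± 0.80 and -7.49 ± 0.87) and argk-1 (-8.55 ± 0.98 and -8.34 ± 0.96) were lower at 12 h and 24 h. Higher on MYb115 were spp-1 (2.59 ± 0.47 and 3.76 ± 0.49), the ferritin gene ftn-1 at 24 h (3.42 ± 0.60) and, at 12 h, gst-10 (4.16 ± 0.70), cyp-25A1 (5.52 ± 0.88), vit-6 (2.32 ± 0.54), vit-2 (2.39 ± 0.53) and unc-27 (0.99 ± 0.22).

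Among lists, PMK-1 targets had 9 of 13 lower on MYb115 under BT247 at 24 h (12 adjusted over the list alone; adjusted p = 0.00086 with an estimated correlation). Intracellular pathogen response genes had 35 of 45 lower at 12 h (38 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation) and 7 at 24 h (13, and 0.429). Vitellogenins had 4 of 6 higher at 12 h (6 adjusted over the list alone) and body wall muscle markers 8 of 14 (9 adjusted over the list alone), both with adjusted p = 0.215 under an estimated correlation. On the second principal component, whose high end holds vitellogenins, MYb115 BT247 replicate 3 lay at 78.8 (vit-6 at 32000 CPM), and OP50 BT247 replicates 1 and 3 at -74.7 and -64.3 (1080 and 4080 CPM). Glutathione S-transferases had 12 of 47 higher with 3 lower (17 and 3 adjusted over the list alone; adjusted p = 0.484 with an estimated correlation). The vit-2 (2.38) and vit-6 calls ended in a fit of the compared groups only. At 12 h 746 genes were higher and 1221 lower on MYb115, and at 24 h 279 were higher and 435 lower. With 2 surrogate variables the 12 h split turned to 1477 higher and 1192 lower, and the 24 h counts were 399 and 681. The 12 h counts without the libraries that stood apart were 453 and 790. At 24 h a fit of the compared groups only gave 64 and 280. The 12 h total of 1967 became 1065 and 2979 without OP50 BT247 replicates 1 and 2 and 1260 and 1224 without MYb115 BT247 replicates 2 and 3. The 24 h total of 714 became 1248 without MYb115 BT247 replicate 2 and 451 without OP50 BT247 replicate 2.

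On MYb11 under BT247, dod-24 (5.54 ± 0.48 and 2.85 ± 0.42) and nspg-7.2 (7.31 ± 0.77 and 7.13 ± 0.76) were higher than on OP50 at 12 h and 24 h, and the aspartyl protease gene asp-14 (4.53 ± 0.64) and F55G11.4 (3.40 ± 0.59) at 12 h. The lectin genes clec-58 (-5.18 ± 0.77 and -6.27 ± 0.81) and clec-258 (-6.06 ± 0.96 and -8.32 ± 1.08), argk-1 (-5.60 ± 0.82 and -8.24 ± 0.97) and the cytochrome P450 gene cyp-35B1 (-3.96 ± 0.59 and -3.68 ± 0.59) were lower at both times. Intracellular pathogen response genes were lower in 9 of 45 cases at 12 h (24 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), including pals-29 (-5.03 ± 0.94). In a fit of the compared groups only, the 12 h calls of dod-24, asp-14, clec-58, clec-258, argk-1, cyp-35B1 and pals-29 and the 24 h call of dod-24 ended. In total 73 genes were higher and 67 lower at 12 h, and 9 and 22 at 24 h. DESeq2 gave 229 and 49 in total, a fit of the compared groups only 3 and 17, and surrogate variables 269 at 12 h. The 12 h total of 140 became 406, 50 and 62 without MYb11 BT247 replicates 1, 2 and 3 and 57, 88 and 84 without OP50 BT247 replicates 1, 2 and 3.

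Few genes were called for the comparator strain alone on OP50, which does not show that its effect was small. At 24 h edgeR called 1 gene, the lipase gene fil-2, higher under BT407 than without Bt (5.41 ± 0.79), and DESeq2 called 3. The fil-2 call held whichever library was left out and ended in a fit of the compared groups only (5.46), which called 0 genes. At 12 h edgeR called 0 genes, with 942 at an unadjusted p under 0.05, and DESeq2 called 2.

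Time on OP50 without Bt moved cuticle genes in both directions. The collagen gene col-74 (6.16 ± 1.00) and the cuticlin gene cut-3 (5.68 ± 1.01) were higher at 24 h than at 12 h. By list, 31 of 166 cuticle collagen genes were lower and 2 higher (83 and 9 adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). Sperm protein genes were lower in 5 of 70 cases (58 adjusted over the list alone; adjusted p = 0.479 with an estimated correlation). In all 574 genes were higher and 571 lower at 24 h, against 1229 and 2184 with DESeq2, 124 and 244 with no filter, and 16 and 141 in a fit of the compared groups only. That total of 1145 became 756, 20 and 249 without the 12 h replicates 1, 2 and 3, and 11, 124 and 1785 without the 24 h replicates 1, 2 and 3.

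Variation between libraries of one group was large. The first 3 principal components took 34.9%, 22.2% and 10.9% of the variance, the second running from vit-3, vit-4, pud-3 and fat-7 at its high end to ilys-3, nlp-39 and cut-3 at its low end. Replicate 2 of OP50 BT407, replicate 1 of MYb11 BT407, replicate 3 of MYb115 BT247 and replicate 3 of MYb115 without Bt stood apart from the other 12 h libraries at the high end of that component, at 82, 109.7, 78.8 and 63.8. Only these were removed as standing apart. At the low end OP50 BT247 replicates 1 and 3 (-74.7 and -64.3) and MYb11 BT247 replicate 1 (-65.1) lay about as far out and were kept. Along the time course of OP50 worms without Bt, the BT247 comparison on OP50 had a slope across genes of -0.51 at 24 h (jackknife standard error 0.264) and 0.062 at 12 h (0.319).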

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

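The tests of explanations in this part were chosen only after the result was seen. The results collected here were picked out because a test of the difference itself found that the response to BT247 differed between foods. Against OP50, the response on MYb11 differed in 1 gene at 12 h and 2 genes at 24 h, and the response on MYb115 in 184 and 272 genes. Gene lists that differed with an estimated correlation were, on MYb11, the propionate shunt (adjusted p = 0.0392) and the methionine cycle (0.0141) at 12 h and PMK-1 targets (0.0463) at 24 h. On MYb115 they were the methionine cycle at 12 h (0.0362) and, at 24 h, PMK-1 targets (0.000133) and the ZIP-2 and translation-inhibition list (0.00118). Genes whose difference in log2 response was called, with at most 2 single libraries able to end the call, were on MYb11 F10D2.8 (-4.13 at 24 h). On MYb115 at 12 h they were ZK896.5 (-2.96), F14F9.3 (-4.84), pcp-1 (1.57), elo-2 (2.37) and ech-6 (1.68). At 24 h on MYb115 they were clec-67 (-5.68), C17H12.8 (-4.91), lys-2 (-5.90), skr-3 (-1.71), cpr-3 (-4.56), ZK896.5 (-5.20), F14F9.3 (-3.25) and acds-10 (1.38). The 12 h calls of ZK896.5 ended without MYb115 BT247 replicate 1 (-2.58), of ech-6 without OP50 BT407 replicate 1 (1.43), and of elo-2 without OP50 BT247 replicate 1 (2.18) or MYb115 BT247 replicate 1 (2.12).

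The response to BT247 was smaller on MYb115 than on OP50. Lower depth argues poorly for it, since the MYb115 libraries under BT247 or BT407 averaged 1.04 times the counts of those on OP50. Other explanations were tested on genes higher on MYb11 at the other time, since genes chosen on OP50 favour OP50. A mislabelled library does not account for the 12 h difference: all 3 MYb115 BT247 libraries scored above the highest MYb115 BT407 library (1.46) and below the lowest OP50 BT247 library (4.38). At 24 h only 2 of the 3 did so. The lowest scored 1.23, under the highest BT407 library (1.68), so a wrong label there stays open, though the highest (2.16) was also below every OP50 BT247 library (3.74 or more). A wider replicate spread hiding an equal response is set against a difference between the responses of 1.97 at 12 h, with a standard error of 0.27, and of 2.22 at 24 h, with a standard error of 0.35. Over genes chosen on OP50 the 24 h difference was 0.82 with a standard error of 0.42, so for those genes it does not exclude an equal response at that time. That the worms on MYb115 took up less toxin or resisted it better stays open, as untested.

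The BT247 comparison on OP50 at 24 h ran against the time course, with a slope of -0.51 (jackknife standard error 0.264). Of the 717 higher genes 510 were also called at 12 h, where the slope was 0.062 (jackknife standard error 0.319). A slope this uncertain does not show that the 12 h comparison was free of a difference in maturity. Such a difference as the whole source of the calls therefore stays open. Among genes called in neither BT247 comparison on OP50 the slope was -0.50 (jackknife standard error 0.29). It has the sign that less mature BT247 worms at 24 h would give, but lies under 2 standard errors from 0. That error pools the 12 left-out libraries without regard to their group. A jackknife within groups was not run and could place the slope on the other side of this limit. Lower maturity as a part of the difference thus stays open. Whether BT247 slowed development or the groups differed at the start was not tested.

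A shared group of 22 genes was called lower on both Pseudomonas foods than on OP50 at 12 h without Bt. Both comparisons used the same OP50 libraries, and noise in these libraries was not excluded as a source of the overlap. A difference in maturity between the foods stays open. The levels of 20 of the 22 on both foods lay below both the 12 h and the 24 h level on OP50, which a state between these times would not give. All 22 also fell from 12 h to 24 h on OP50, though, and a state past 24 h was not measured. These genes were picked for being low on both foods. As a hypothesis, the Pseudomonas foods may supply more vitamin B12, which is known to lower the propionate shunt. By the sign of the mean alone, all 9 of its tested members were lower on both foods at 12 h, and 6 of the 9 at both times. The largest change was that of acdh-1, at -7.73 on MYb11 and -7.12 on MYb115 at 12 h and -7.29 and -2.74 at 24 h. It was not among the 22 shared genes. At 12 h 2 members were called on MYb11 and 3 on MYb115, and the set test with an estimated correlation passed on MYb11 (adjusted p = 0.037) and not on MYb115 (0.609), so the tables leave this open. No measurement of vitamin B12 was analysed here.

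Other divisions of the same libraries were fitted for the differences between responses. For MYb115 the real division called 902 genes at 12 h and 221 at 24 h in a fit of the compared groups, with 4 and 2 of 40 divisions reaching as many and the highest other at 1413 and 1637, so chance is not excluded at either time by this count. For MYb11 the real division called 0 at both times, which every division reaches (40 of 40), so this count decides nothing. The highest others were 1781 and 1612. Food labels were exchanged separately under BT247 and under BT407, so a division can pick up a difference between the foods themselves. Divisions that call far more than the real one therefore do not tell chance from the effect of the foods or from other structure.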

How the results depend on the processing

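The removal of shallow libraries, the removal of libraries that stood apart and the surrogate variables were chosen only after the data were seen, and the cause of each change was not tested. No named gene's call was reversed under the alternatives. RLE factors moved no count by more than 1.5-fold. Of 190 calls of named genes, all were kept with DESeq2, RLE factors and the replicate block, 184 without a filter, 189 with the stricter filter, 188 with surrogate variables and 127 in a fit of the compared groups only. In 162 no single library ended the call, but the genes were in part picked for this, so it says nothing about genes in general.

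Counts with DESeq2, at 12 h and 24 h, were 63 and 2 for BT247 on MYb115, 65 and 38 for MYb11 against OP50, 1880 and 672 for MYb115 against OP50, 229 and 49 for MYb11 against OP50 under BT247, and 6 and 14 for the MYb11 difference between responses. They were 61 and 24 for MYb115 against MYb11, and 2 and 3 for BT407. The MYb115 difference at 12 h had 407 and time 3413. In a fit of the compared groups only BT247 on MYb11 had 168 higher and 14 lower (1.8e+02 together) at 12 h and 71 at 24 h. The others were 0 for BT247 on MYb115 at 12 h, 2 and 3 for MYb11 against OP50, 17 and 4 for MYb115 against OP50, 3 and 17 for MYb11 under BT247, and 344 for MYb115 under BT247 at 24 h. They were 0 and 0 for the MYb11 difference, 902 for the MYb115 difference at 12 h, 0 and 3 for MYb115 against MYb11, 0 for BT407 at 24 h and 157 for time. With no low-count filter the counts were 365 and 13 for MYb115 against OP50, 0 for the MYb11 and 113 for the MYb115 difference at 12 h, 7 for MYb115 against MYb11 at 12 h and 368 for time. At least 1 CPM in 3 libraries gave 683 and 402 for MYb115 against OP50. The replicate block gave 6 for MYb115 against MYb11 at 12 h.

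With 2 surrogate variables the counts were 80 for BT247 on MYb115, 65 for MYb11 against OP50, 269 for MYb11 under BT247 and 24 for MYb115 against MYb11, all at 12 h. They were 1080 for MYb115 under BT247 and 3 for BT407 at 24 h, 2 and 18 for the MYb11 difference and 361 and 511 for the MYb115 difference. They moved the split of up and down calls from 67.5% to 48.4% up for BT247 on OP50 at 12 h (median of all genes shifted by -0.197), and from 90.7% to 511 up and 128 down for BT247 on MYb11 at 12 h (-0.118). Likewise the share went from 37.9% to 55.3% for MYb115 under BT247 at 12 h (0.115), from 27.7% to 62.3% for the MYb115 difference at 12 h (0.237), and from 61.3% to 46.9% for MYb115 against OP50 at 24 h (-0.144). It went from 45.5% to 62.5% for MYb115 against MYb11 at 12 h (0.106), and BT407 at 12 h shifted by 0.129. DESeq2 moved the share up to 79.9% for MYb115 against OP50 at 24 h, 36.0% for time, 65.6% and 33.3% for MYb115 against MYb11 and 50.0% and 21.4% for the MYb11 difference.

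Without the 3 libraries under 25000000 counts, BT247 called 1451 on OP50 at 12 h and 267 and 187 on MYb11, MYb115 against OP50 under BT247 1205 at 12 h, and the MYb11 difference 5 and 9. Without the 4 libraries that stood apart at 12 h, the 12 h counts were 1479 for BT247 on OP50, 3 on MYb115, 526 for MYb115 against OP50, 1243 for MYb115 under BT247, 0 and 121 for the MYb11 and MYb115 differences and 26 for MYb115 against MYb11.

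Leaving out each library in turn gave, at 12 h and then 24 h, 1344 to 3960 for BT247 on OP50 at 12 h, 260 to 585 and 188 to 392 on MYb11, and 3 to 60 and 0 to 1 on MYb115. It gave 16 to 789 and 11 to 95 for MYb11 against OP50, 41 to 1638 and 6 to 28 for MYb115 against OP50, 50 to 406 for MYb11 under BT247 at 12 h, and 1065 to 2979 and 451 to 1248 for MYb115 under BT247. It gave 0 to 6 and 1 to 5 for the MYb11 difference, 65 to 181 for the MYb115 difference at 12 h, 3 to 73 and 4 to 11 for MYb115 against MYb11, and 11 to 1785 for time. An estimated correlation reduced list calls from 280 to 16. At an adjusted p of 0.01 the foods shared 1 higher and 14 lower genes at 12 h and 4 lower at 24 h.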

Other observations

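The tests over other divisions of the libraries in this part were judged after the results were seen. Some members of the detoxification lists were called higher on MYb115 than on OP50 under BT247 at 24 h, and none of these lists passed with an estimated correlation. Glutathione S-transferases had 10 of 47 genes higher and 2 lower (24 and 4 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), cytochrome P450 genes 11 of 71 higher and 3 lower (16 and 6 adjusted over the list alone; 0.429) and UDP-glucuronosyltransferases 8 of 66 higher and 2 lower (18 and 4 adjusted over the list alone; 0.429). Of 177 C-type lectins 24 were lower and 7 higher (27 and 10 adjusted over the list alone; adjusted p = 0.584 with an estimated correlation). On OP50 the thaumatin gene thn-2 fell under BT247 at 24 h (-4.75 ± 0.80) and was not called at 12 h (-0.69 ± 0.69).

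Divisions of 3 against 3 libraries are too few to exclude chance, since 1 division in 10 is the real one, and a real count of 0 is reached by every division. For BT247 on OP50 the real division called 2091 genes at 12 h (1 of 10 divisions as large, highest other 0) and 860 at 24 h (2 of 10, highest other 1332). On MYb11 it called 168 higher and 14 lower genes at 12 h and 71 genes at 24 h (1 of 10 each, highest other 0), and on MYb115 0 and 0 (10 of 10 each, highest other 0 and 496). Without Bt, MYb11 against OP50 gave 2 and 3 and MYb115 against OP50 gave 17 and 4, each with 1 of 10 as large and a highest other of 0. Under BT247, MYb11 against OP50 gave 3 and 17 (2 of 10 each, highest other 6616 and 2977) and MYb115 against OP50 1462 and 344 (1 of 10 each, highest other 0). MYb115 against MYb11 gave 0 (10 of 10, highest other 0) and 3 (1 of 10, highest other 0), BT407 against no Bt 0 and 0 (10 of 10 each, highest other 32 and 0), and the time comparison 157 (1 of 10, highest other 0). The highest others of 6616 and 2977 point to structure among the OP50 and MYb11 libraries under BT247 that the groups do not describe.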
